A study of Mus musculus with 28 samples.

How the data were processed

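The series holds 28 mouse samples. The 9 analysed here are RNA-seq libraries from splenic CD4+ T cells of wild-type C57BL/6 mice, 1 library per condition: a control without cytokine, and cells treated with either IL-2 or IL-21 and collected at 4 times (0.5, 2, 4 and 24 h). Per the labels' protocols, T cells were isolated from spleen with magnetic kits, activated for 3 days on plates coated with anti-CD3 (2 µg/ml) together with anti-CD28 (1 µg/ml), rested overnight and then treated. The labels state cytokine doses for the chromatin cultures and do not repeat them for RNA-seq, so no dose is attached to the values here. The other 19 samples are chromatin immunoprecipitation libraries and are not analysed here. Groups came from the sample labels. No control library at 2, 4 or 24 h is analysed here, so time in culture and cytokine are not separable in comparisons with the control.

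Per the labels' protocols, libraries were made from total RNA with a stranded kit, size-selected and sequenced on Illumina instruments. The submitters' processing notes name the mouse genome build mm9, Bowtie 0.12.9, TopHat2 2.0.11, SAMtools and HOMER, with no role given for each. The annotation, the counting program and whether counting used strand are not given in the sources used here. Per the file headers, each deposited file lists RefSeq transcripts with chromosome, strand, length, a read count and an RPKM value (reads scaled to transcript length in kilobases and to the library's total). The deposited counts are whole numbers per transcript. In the deposited files every RPKM equals the count times a constant divided by transcript length, with 1 total per library that was whole to within 0.01 reads. These totals ran from 29.5 to 44.3 M reads. A file holds 29543 transcripts of 23222 gene symbols, 3961 of which have several transcripts, and reads of shared exons are counted for each of them. Of the transcript identifiers, 28929 were found in a RefSeq gene table of assembly GRCm38.p6, and 2924 of those carry a newer symbol there. Symbols are given as in the files, and no coordinates were taken from that table because its build differs.

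Each gene was represented by its transcript with the highest mean RPKM over the 9 libraries. Symbols of microRNAs, small nuclear, small nucleolar and related short RNAs (743) were left out, because reads per kilobase are not comparable for transcripts shorter than the sequenced fragments. The rule went by symbol and also left out the ribosomal precursor RNA Rn45s, which is no short RNA, so that reason does not apply to it. A difference between 2 libraries was taken as log2(RPKM + 1) in one minus the other, over the 11047 genes whose highest library reached 1 RPKM. The pseudocount of 1 understates changes of low genes. Genes were counted at a difference of 2-fold or more. With 1 library per condition such a difference has no replicate check, and no p-value is given for it. Ratios of RPKM carry an exact 95% interval from the conditional binomial distribution of the 2 read counts. These intervals, and the floor that 3 reads set for a gene without reads (0.0677 to 0.102 RPKM for a transcript of 1 kb), cover counting error only, since reads without molecular identifiers are not independent molecules.

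The cytokines were also compared over the 4 times together, using the 8 cytokine libraries with time as a factor, which leaves 3 residual degrees of freedom. The mean cytokine difference is thereby set against its own variation between times. The planned test was limma on log2(RPKM + 1). Because the files also hold read counts, the main test became edgeR's quasi-likelihood test on the deposited counts with trimmed-mean (TMM) scaling and Benjamini-Hochberg adjustment, and limma is reported as an alternative. The same edgeR fit gave the contrast of 24 h with 0.5 h over both cytokines. Tests used the 10452 genes with a mean of at least 1 RPKM, and adjusted p below 0.05 was the threshold. Nothing in the labels says that the libraries came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be partly technical.

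There were 28 gene lists: targets of STAT5 and of STAT3, JAK-STAT components, receptors of the common gamma chain family, Th1 and cytotoxic, Th2, Th17, Tfh, Treg, naive and quiescence, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, interferon-stimulated, immediate early, apoptosis, amino acid stress (ATF4) and housekeeping genes, neighbours of Il2ra, nuclear and non-polyadenylated RNA, and markers of B, CD8 T, CD4 T, macrophage, dendritic, NK and erythroid cells. Lists were tested for IL-2 against IL-21 with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. For 2 libraries a list is described by its median difference and by the percentile of that median among 10000 random lists of the same size matched on mean expression. The random genes were drawn singly, so this percentile takes no account of correlation between the members of a list.

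The named genes are Il2ra; the 3 genes with the largest positive and the 3 with the largest negative difference from control at each time, among genes reaching 5 RPKM in either library; the 10 largest in each direction for IL-2 against IL-21, taking those past the threshold before the others and requiring the same sign at all 4 times; the 4 members of each described list with the largest difference at the time of its most extreme median; and all listed neighbours of Il2ra. Not every gene that the rule selects is named. Genes named outside this rule are said to be chosen after their values were seen. The groups, lists, named-gene rule, thresholds and most alternative settings were set before the data were examined.

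The alternative settings were other pseudocounts (0.1 and 0.5), other expression filters, median-ratio and upper quartile scaling, averaging a gene's transcripts, keeping short RNAs, taking the 0.5 h library of the same cytokine as reference, limma with trend and robust options, a fit without time, and leaving out the libraries of 1 time. DESeq2, edgeR's robust option, a difference restricted to 4 and 24 h and a requirement on the counting interval were added after seeing the data. The edgeR script was tested on simulated data over 10452 genes for IL-2 against IL-21 over 4 times. It recovered 22% of 50 genes changed 1.5-fold and 62% of 50 changed 2-fold. It recovered 98% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 7 false calls among 10252 unchanged genes. Each simulated fold was the same at all 4 times. These shares therefore do not hold for differences that change with time, since that change goes into the error. The 2-library script, tested at the depth of the control library with counting noise alone, recovered 200 of 200 genes changed 4-fold and called 0 unchanged genes. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.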

Results

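RNA was sequenced from mouse CD4+ T cells that had been activated through the T cell receptor, rested, and then left without cytokine or exposed to IL-2 or IL-21. Both cytokines signal through receptors that contain the common gamma chain; IL-2 acts mainly through STAT5 and IL-21 mainly through STAT3. The series title concerns the Il2ra locus, STAT5 and genes strongly induced by IL-2, and the RNA libraries address which genes respond to each cytokine and when. There was 1 library without cytokine and 1 for each cytokine at 0.5, 2, 4 and 24 h. With 1 library per condition, comparisons of 2 libraries carry no p-values. The authors' total was 34.4 M reads for the control, 29.5, 34.8, 40.4 and 31.0 M for IL-2 at the 4 times in order, and 34.3, 44.3, 39.1 and 37.9 M for IL-21. At these depths 1 read in a transcript of 1 kb is worth 0.0226 to 0.0339 RPKM.

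More genes differed from control the longer cells had been with IL-2, and far fewer differed with IL-21 after 24 h. Against control, 48 of 11047 genes differed by at least 2-fold after 0.5 h of IL-2 (44 higher, 4 lower), 492 after 2 h (347 higher, 145 lower), 957 after 4 h (593 higher, 364 lower) and 1791 after 24 h (1057 higher, 734 lower). With IL-21, 36 were higher and 6 lower at 0.5 h, 189 and 130 at 2 h, 134 and 146 at 4 h, and 179 and 206 at 24 h. In every one of these 8 comparisons with control all counted genes had a 95% counting interval that excluded equal levels. The rule of 2-fold after adding 1 RPKM nearly ensures this at these depths. The split by direction depended on scaling: with upper quartile scaling the IL-2 counts were 476 higher and 484 lower at 4 h, and 668 higher and 1062 lower at 24 h. That scaling moved the median of all genes by -0.18 (log2) for IL-2 at 24 h against control.

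**Figure D1:**
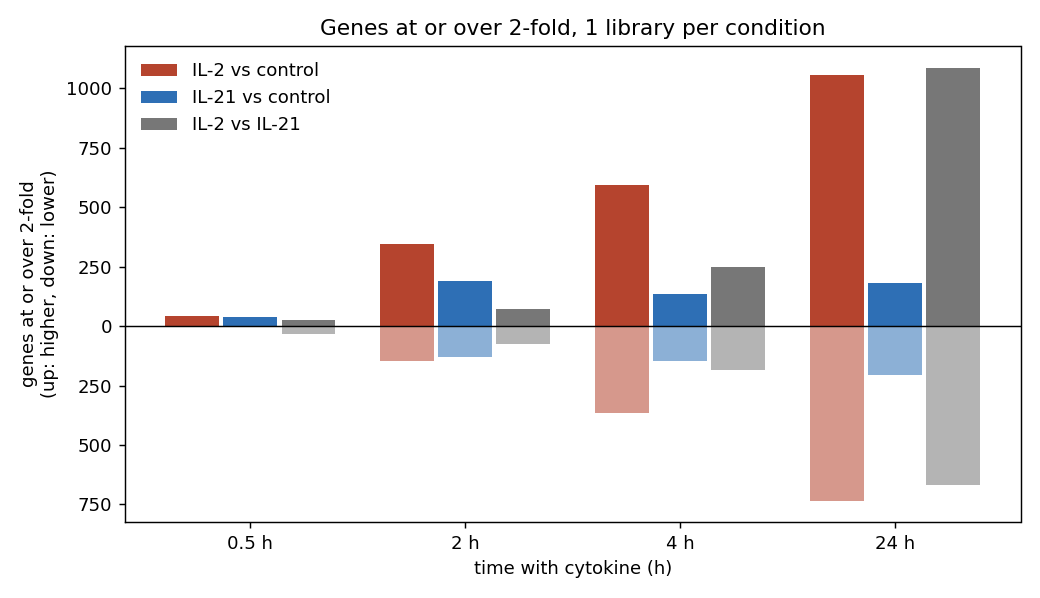
Bars give the number of genes at or over 2-fold (vertical axis; upward higher, downward lower) by time with cytokine in hours, for IL-2 against control, IL-21 against control and IL-2 against IL-21, with 1 library per condition. The IL-2 bars grow to 1057 higher and 734 lower genes at 24 h, while the IL-21 bars stay at 179 higher and 206 lower.

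Il2ra (NM_008367, plus strand of chromosome 2 in mm9), which encodes the IL-2 receptor alpha chain, stood at 78.5 RPKM in the control and at 80.5 and 81.0 RPKM after 0.5 h of IL-2 and IL-21. After 2 h it was at 302 RPKM with IL-2, 3.85 times the control (95% counting interval 3.77 to 3.93), and at 278 RPKM with IL-21, 3.54 times the control (3.47 to 3.61). From there the series parted. With IL-2 the level was 433 RPKM at 4 h and 596 RPKM at 24 h, 5.52 and 7.60 times the control. With IL-21 it was 187 RPKM at 4 h and 109 RPKM at 24 h, 2.38 and 1.38 times the control. The ratio of IL-2 to IL-21 was thus 1.09 at 2 h, 2.32 at 4 h and 5.49 at 24 h (5.41 to 5.58). Over the 4 times together the difference of 0.88 (log2, SE 0.42) did not pass (edgeR adjusted p = 0.369), with IL-2 higher at 3 of 4 times.

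The listed genes around Il2ra did not reach 2-fold from control as it did, though smaller differences were seen. Of the 8 measured genes on the neighbour list, the files place Il2ra and 6 others on chromosome 2 and Gdi2 on chromosome 13, so Gdi2 is no neighbour. The 6 neighbours, Il15ra, Fbxo18, Ankrd16, Rbm17, Pfkfb3 and Prkcq, included 0 at or over 2-fold from control at any time under either cytokine. Pfkfb3, a regulator of glycolysis, was at 13.9 RPKM after 24 h of IL-2 against 7.4 in control. Il15ra, which encodes the IL-15 receptor alpha chain, was at 17.4 RPKM after 2 h of IL-2, 14.0 after 2 h of IL-21 and 9.7 in control. Prkcq, which encodes protein kinase C theta, was the only neighbour at or over 2-fold between the cytokines, with 52.3 RPKM after 24 h of IL-2 and 121 RPKM after 24 h of IL-21. Rbm17 was at 77.9, 43.7 and 55.4 RPKM after 24 h of IL-2, 24 h of IL-21 and in control. In the same order Fbxo18 was at 7.5, 9.0 and 11.8 RPKM, and Ankrd16 at 4.9, 6.5 and 7.3. The ratio of IL-2 to IL-21 for Rbm17 was 1.13, 1.38, 1.43 and 1.78 at 0.5, 2, 4 and 24 h. That ratio rose with time as the ratio for Il2ra did, but stayed smaller at 4 and 24 h. As a list, the 8 genes did not stand apart in the camera test of IL-2 against IL-21 (camera adjusted p = 0.588). Adjusted over the list alone, 0 genes passed. The list holds Il2ra and Gdi2, so the test does not decide whether the 6 neighbours follow Il2ra.

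**Figure D2:**
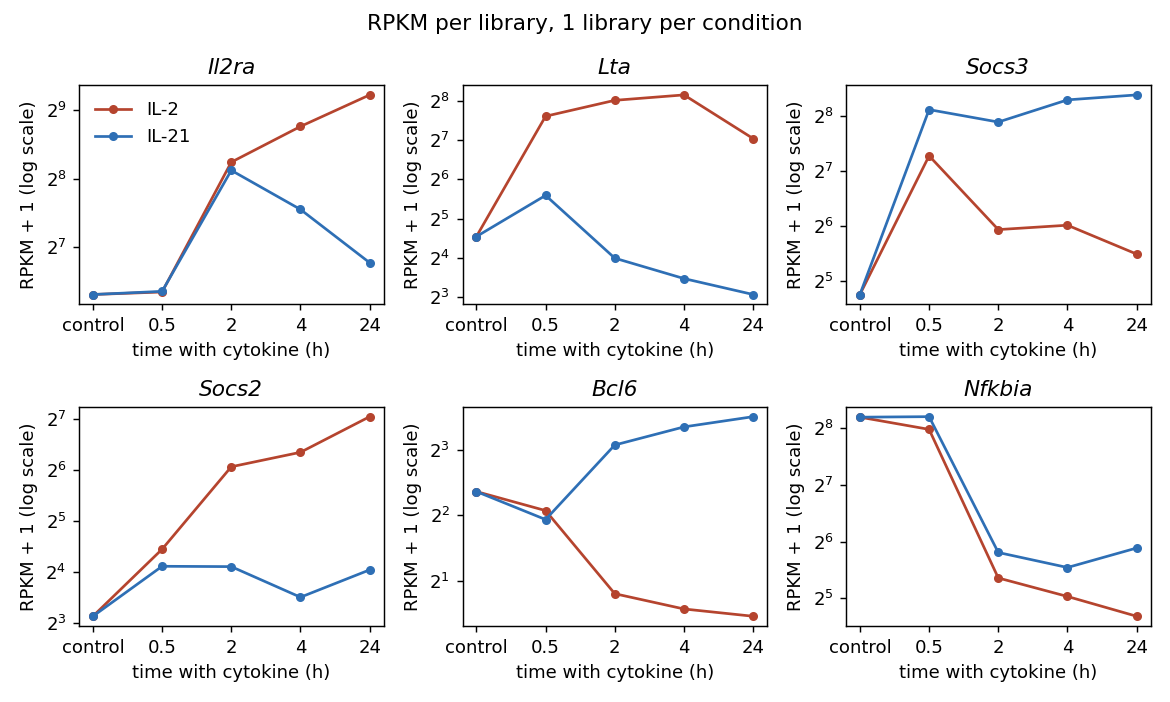
RPKM + 1 on a log scale (vertical axis) in the control and after 0.5, 2, 4 and 24 h of cytokine (horizontal axis) for 6 genes, with IL-2 and IL-21 as separate lines and each point 1 library. Il2ra reaches similar levels at 2 h (302 and 278 RPKM) and parts afterwards, while Nfkbia is lower than control (292 RPKM) with both cytokines from 2 h on.

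Within 0.5 h of IL-2 the 3 largest positive differences were in Lif, Id1 and Lta. Lif, an IL-6 family cytokine, was at 58.5 RPKM against 2.48 in control (log2 difference 4.09). Lta, which encodes lymphotoxin alpha, was at 194 against 22.4 RPKM (3.06), and Id1, an inhibitor of helix-loop-helix factors, at 20.1 against 0.543 RPKM (3.77). The 3 largest negative differences were in Tgif1 (-1.34), Id3 (-1.17) and Arrdc3 (-1.16). The immediate early genes, transcription factors and signalling genes induced without new protein synthesis, had a median difference of 0.81 over 19 genes, above all 10000 matched random lists, with 5 at or over 2-fold higher. Among them Egr1 was at 43.1 against 5.0 RPKM, Myc at 269 against 65.1, Ier3 at 22.5 against 5.3 and Fos at 6.6 against 1.7.

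Lif and Lta, both cytokine genes, stayed among the largest positive differences with IL-2. At 2 h their differences were 3.96 and 3.47, and at 4 h 4.19 and 3.60. Lama5, the laminin alpha 5 gene, joined them at 3.05 and 3.33. The largest negative differences at both times were in NF-kappaB feedback inhibitors and a T cell activation gene: Nfkbia (-2.84 at 2 h and -3.16 at 4 h), Tnfaip3 (-2.76 and -3.25) and Tagap (-2.67 and -2.92). Nfkbia went from 292 RPKM in control to 40.0 RPKM at 2 h. At 24 h the largest positive differences were in Myo6, an unconventional myosin (41.5 against 0.717 RPKM, 4.63), Lif (4.51) and Enah, an actin regulator (18.2 RPKM, against 8 reads in control, 4.17). The largest negative ones were in Mxd4, a MYC antagonist (-3.61), Nfkbia (-3.51) and Tcp11l2 (-3.48).

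STAT5 target genes were higher with IL-2 at every time, with medians over 22 genes of 0.35, 0.65, 1.02 and 0.79 at 0.5, 2, 4 and 24 h. At 4 h 11 of the 22 were at or over 2-fold higher and 0 lower, including Lta, the feedback inhibitor Socs2 (80.7 against 7.7 RPKM) and the cytokines Il24 (16.4 against 0.9) and Osm (69.0 against 10.2). Ribosome biogenesis genes had medians of 1.45, 1.74 and 1.54 at 2, 4 and 24 h, with 13, 14 and 14 of 18 at or over 2-fold higher. At 4 h the RNA polymerase I subunit gene Polr1b was at 23.3 against 3.8 RPKM, Rrp12 at 19.0 against 3.1, Gnl3 at 69.9 against 14.0 and Nop2 at 57.4 against 11.5. The receptors of the common gamma chain family had a median of 0.30 at 4 h over 7 genes, with Il2ra higher by 2.45, Il2rb higher by 0.83, Il4ra higher by 0.45 and Il7r, the IL-7 receptor alpha chain, lower (69.4 against 170 RPKM, -1.28). Treg genes had a median of 0.31 at 4 h over 10 genes, with Lrrc32 (41.1 against 8.5 RPKM), Gpr83 (13.8 against 2.5) and Il10 (9.2 against 3.8) higher and Tigit (9.8 against 32.4) lower.

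At 24 h of IL-2, genes of growth and division were higher together. Of 24 cell cycle genes 20 were at or over 2-fold higher (median 1.38), among them the replication genes Mcm2 (112 against 26.2 RPKM), Rrm2 (193 against 51.6), Ccne1 (28.9 against 7.8) and Cdc6 (24.6 against 7.0). Cholesterol synthesis genes had a median of 1.49 with 11 of 16 at or over 2-fold higher, such as Idi1 (56.9 against 11.5 RPKM), Cyp51 (37.3 against 8.0) and Sqle (39.0 against 8.9). Glycolysis genes had a median of 1.07 with 9 of 17 higher, led by the lactate transporter gene Slc16a3 (79.7 against 14.6 RPKM), Hk2 (26.1 against 5.2), the glucose transporter gene Slc2a1 (63.5 against 15.0) and Pgam1 (351 against 91.6). Amino acid stress genes, targets of ATF4, had a median of 1.12 with 7 of 12 higher, led by the transporter gene Slc7a5 (44.6 against 9.9 RPKM) and the serine pathway genes Phgdh (109 against 31.6), Psat1 (86.3 against 25.6) and Shmt2 (59.7 against 20). Each of these 4 medians lay above at least 99.99% of matched random lists, which make no allowance for members that move together. Housekeeping genes were higher as well (median 0.72, 4 of 14 at or over 2-fold), among them the transferrin receptor gene Tfrc (134 against 16.4 RPKM), Hprt (136 against 45.4) and Gusb (1.19). B cell markers were lower in the same library, with a median of -0.76.

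Th2 genes were higher too, with a median of 1.52 and 5 of 7 at or over 2-fold: Il24 (31.4 against 0.9 RPKM), Il13 (20.5 against 2.8), Il5 (3.21 against 0.09) and Il4 (18.9 against 6.0) differed most. Naive and quiescence genes were lower (median -1.26, 9 of 15 at or over 2-fold), led by Pik3ip1 (5.6 against 50.2 RPKM), the antiproliferative gene Btg1 (26.5 against 183), Txnip (58.9 against 323) and Tcf7, a transcription factor of resting and memory T cells (-2.09). Tfh genes had a median of -0.82, with 3 of 10 at or over 2-fold lower, namely Tcf7, the lineage regulator Bcl6 (0.37 against 4.14 RPKM) and Cxcr5 (1.4 against 5.1), and with Icos higher (109 against 45.8). Interferon-stimulated genes had a median of -0.94, with 9 of 22 lower, including Irf1 (55.2 against 252 RPKM), Irf7 (3.7 against 18.9), Ifit1 and Mx1. Th17 genes had a median of -0.68 over 6 genes, with Rora at -1.10, and JAK-STAT components one of -0.47 over 14 genes, with Jak2 (33.2 against 79.6 RPKM) and Stat4 (22.4 against 52.7) lower. Among apoptosis regulators (median -0.48, 14 genes) the survival gene Bcl2 was higher (93.2 against 18.9 RPKM) and the death-promoting genes Bbc3 (3.5 against 18.8), Bcl2l11 (8.0 against 29.0) and Fas (8.7 against 24.4) were lower. The B cell marker median of -0.76 also stands beside these groups, and no 24 h library without cytokine was compared.

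The early differences with IL-21 overlapped those with IL-2. After 0.5 h of IL-21 Socs3, the feedback inhibitor induced by STAT3, was at 275 RPKM against 26.1 in control (log2 difference 3.35), the stress-response gene Gadd45g at 172 against 19.6 (3.07) and the anti-inflammatory cytokine gene Il10 at 25.0 against 3.79 (2.44). With IL-2 at 0.5 h these genes were higher than control too, at 153.4, 96.4 and 8.8 RPKM. The largest negative differences were in the phosphatase gene Dusp2 (-1.56), Id3 (-1.42), also among the lowest with IL-2, and Ddit4 (-1.37). Socs3 remained high at 2 h (3.12), 4 h (3.52) and 24 h (3.61). B4galnt4 (2.66) and Cpd (2.65) followed it at 2 h, and Igfbp4 (3.51) and Lama5 (2.77) at 4 h. At 24 h Igfbp4, which encodes an insulin-like growth factor binding protein, was at 497 against 30.6 RPKM (3.98) and Serpinb5 at 19.1 against 0.817 RPKM (3.47).

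With IL-21 at 2 and 4 h the largest negative differences were in the early activation marker gene Cd69 (-2.53 and -2.91), the AP-1 gene Fosb (-2.46 and -2.75) and Tagap (-2.48 and -2.71). At 24 h they were in Fam183b (5 reads against 181 in control, -3.07), Serpinf1 (3.25 against 33.4 RPKM, -3.02) and Fosb (-2.78).

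STAT3 target genes were higher with IL-21 at every time, with medians over 17 genes of 0.51, 0.58, 0.30 and 0.43. At 2 h 5 of 17 were at or over 2-fold higher, including Socs3, the IL-21 receptor gene Il21r (232 against 66.4 RPKM), Ahr (6.7 against 1.3) and Il10 (13.9 against 3.8). With IL-2 the same list was at 0.30 at 0.5 h and at -0.50 at 24 h, where Bcl6 and Il6ra were lower and Il10 and Icos higher. STAT5 target genes with IL-21 had medians between 0.25 and 0.32 at the 4 times, each above at least 99.98% of matched random lists. At 0.5 h 6 of 22 were at or over 2-fold higher and 0 lower. By 24 h 2 were higher (Gadd45g and Gzmb) and 3 lower, among them Lta and Tnfrsf4. JAK-STAT components had a median of 0.07 at 2 h, with Stat5a (89.1 against 35.0 RPKM) higher and Stat4 (18.9 against 52.7) lower. Ribosome biogenesis genes were higher at 2 h (median 1.00, 8 of 18 at or over 2-fold) and lay closer to control at 24 h (0.39, 0 higher). Th2 genes were lower at 4 h (median -0.87), with Gata3 (-1.34), which encodes the Th2 lineage regulator, Ccr8 (-1.25) and Il4 (-1.05) at or over 2-fold.

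Th1 and cytotoxic effector genes had the highest list median after 24 h of IL-21, 1.59 over 16 genes, above all matched random lists. Of these, 9 were at or over 2-fold higher, led by the chemokine gene Ccl4 (17.0 against 0.75 RPKM), the IL-18 receptor genes Il18r1 (20.3 against 2.3) and Il18rap (14.6 against 2.1), and the transcription factor gene Hlx (11 against 1.4). Tfh genes had a median of 0.38 with Bcl6 (10.4 against 4.14 RPKM) and Btla (28.0 against 13.0) at or over 2-fold higher and Tcf7 higher by 0.95 at 607 RPKM. Naive and quiescence genes were 0.22 above control at 24 h after -0.58 at 4 h, cell cycle genes 0.43 below it (-0.43, 0 of 24 at or over 2-fold), and glycolysis genes at -0.35. B cell markers were lower in the same library, by more than with IL-2: the median over 9 genes was -1.44, and 7 were at or over 2-fold lower. The medians of 3 other marker lists lay above control there, but their members were split. The 3 NK markers had a median of 0.85 (99.86th percentile of matched random lists), with Eomes lower (-0.23). Gzma and Eomes are also on the Th1 and cytotoxic list. The 5 macrophage markers had a median of 0.55 (99.66th), with 3 higher, 2 lower and 0 at or over 2-fold. The 2 CD8 markers had a median of 0.51 (94.26th), with Cd8a at 1.01 and Cd8b1 at 0.01.

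**Figure D3:**
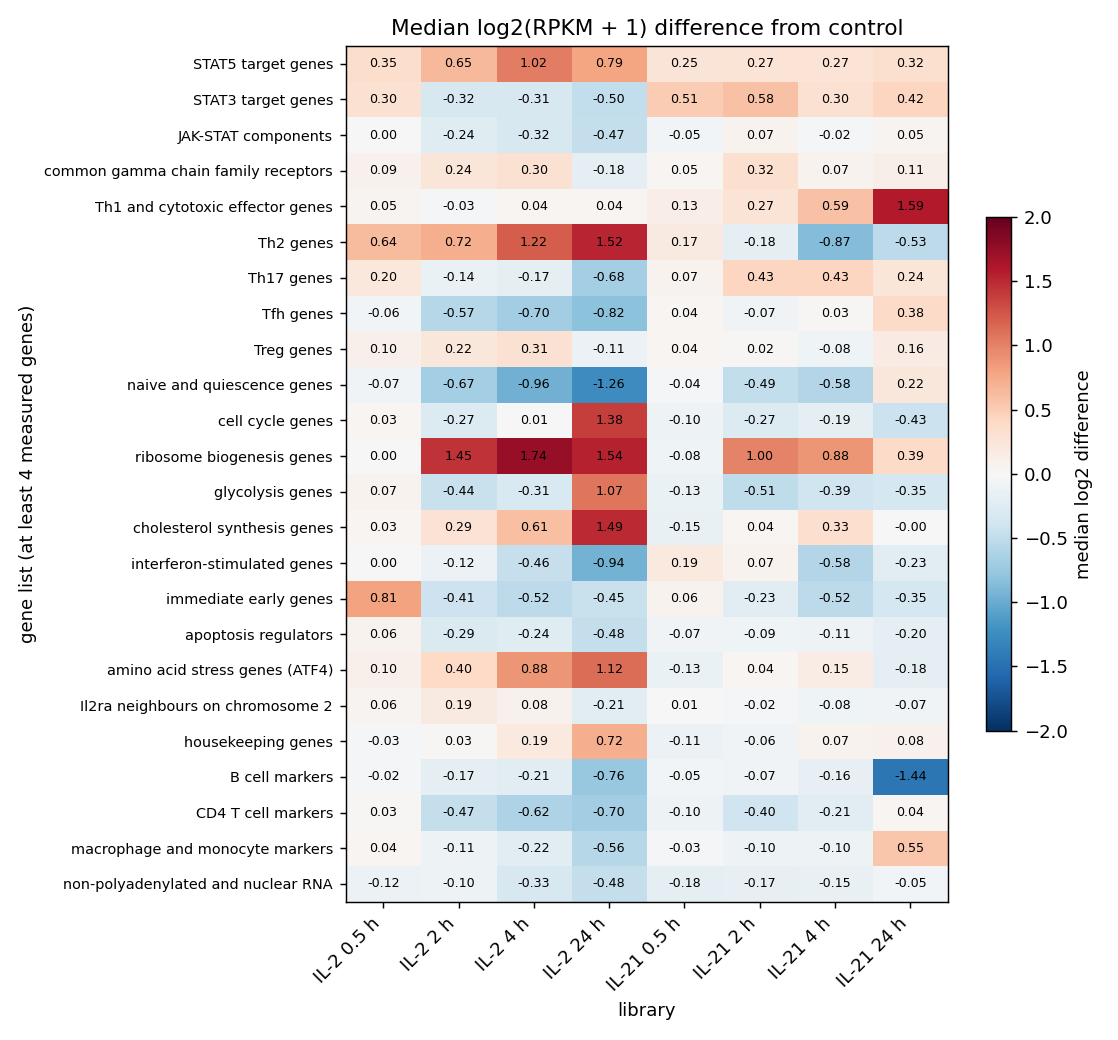
Each cell gives the median log2(RPKM + 1) difference from control of a gene list (vertical axis, lists with at least 4 measured genes) in 1 library (horizontal axis), coloured red above and blue below 0. Ribosome biogenesis genes stand out from 2 h of IL-2 on (1.45 to 1.74), cell cycle genes at 24 h of IL-2 (1.38) and Th1 and cytotoxic genes at 24 h of IL-21 (1.59).

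Markers of other cell types gave the following levels. B cell markers were present in the control, with Cd79b at 16.5, Ms4a1 at 13.8 and Cd79a at 11.7 RPKM. After 24 h they were at 5.9, 6.2 and 5.1 RPKM with IL-2 and at 3.3, 1.5 and 1.8 RPKM with IL-21, while the list medians at 2 h were -0.17 and -0.07. CD4 T cell markers, among them Cd4, Cd5, Cd3d and Cd3g, had a median of -0.70 after 24 h of IL-2 and of 0.04 after 24 h of IL-21. Of the CD8 markers, Cd8b1 was at 9.2 RPKM and Cd8a at 0.55 RPKM in control, with a median difference of 0.51 after 24 h of IL-21. Macrophage markers were low (Cd68 3.8 and Tyrobp 2.4 RPKM in control), with medians of -0.57 and 0.55 after 24 h of IL-2 and IL-21. The 3 measured NK markers had a median of 0.85 after 24 h of IL-21, where Gzma, which T cells also express, was at 519 against 192 RPKM. Dendritic markers Itgax and Flt3 did not exceed 1.1 RPKM (median difference -0.63 after 24 h of IL-2). The hemoglobin genes Hbb-b1 and Hbb-b2, near-identical copies whose split is uncertain, were at 1.2 RPKM in control and 0.1 after 24 h of IL-2 (median difference -1.01). Nuclear and non-polyadenylated RNAs had a median of -0.48 after 24 h of IL-2, with Malat1 at 64.0 against 138 RPKM and the histone gene Hist2h2aa1 at 15.7 against 6.4.

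Set side by side at matched times, the cytokines differed by at least 2-fold in 56 genes at 0.5 h (24 higher with IL-2, 32 lower), 147 at 2 h (71 and 76), 431 at 4 h (247 and 184) and 1757 at 24 h (1087 and 670). With upper quartile scaling the split was 202 higher and 221 lower at 4 h, and 735 higher and 1014 lower at 24 h. At 24 h all 24 cell cycle genes were at or over 2-fold higher with IL-2 than with IL-21, as were 13 of 16 cholesterol synthesis genes, 13 of 17 glycolysis genes and 13 of 18 ribosome biogenesis genes. In the other direction 11 of 15 naive and quiescence genes and 9 of 16 Th1 and cytotoxic genes were at or over 2-fold lower with IL-2. B cell markers were higher with IL-2 at 24 h by a median of 0.87. The medians of macrophage (-0.946), NK (-0.794) and CD8 (-0.744) markers were lower, as that of the Th1 and cytotoxic genes was. Of the NK markers, Gzma and Klrc1 were lower with IL-2 and Eomes was higher (2.5 against 0.7 RPKM).

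Over the 4 times together, 4 of 10452 genes differed between IL-2 and IL-21 in edgeR's quasi-likelihood test. Hbegf, an epidermal growth factor receptor ligand, was higher with IL-2 by 3.34 (log2, SE 0.25; edgeR adjusted p = 0.0335), with mean levels of 3.11 and 0.332 RPKM. Tnf, the inflammatory cytokine tumour necrosis factor, was higher by 2.4 (SE 0.21; edgeR adjusted p = 0.0377), at 32.6 and 6.32 RPKM. Zfp36, whose product binds and destabilises AU-rich messenger RNAs, was lower with IL-2 (-2.15, SE 0.14; edgeR adjusted p = 0.0206), at 18.7 and 77.9 RPKM, and the kinase gene Sgk1 was lower (-1.83, SE 0.15; edgeR adjusted p = 0.0335), at 5.68 and 19.8 RPKM. All 4 had the same sign at 4 of 4 times. The count at an unadjusted p under 0.05 was 1524, limma gave 3 genes and DESeq2 447, and the edgeR fit without the 4 h libraries gave 0 genes (690 unadjusted), without the 24 h libraries 0 (1060 unadjusted) and without the 0.5 h libraries 123.

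Larger mean differences did not pass because they varied between times. Lta was higher with IL-2 by 3.75 (SE 0.49, edgeR adjusted p = 0.126) and Lif by 3.46 (SE 0.51, edgeR adjusted p = 0.156). Akr1c18 (3.41), B4galt4 (2.74), Il24 (2.71), Myo6 (2.66), Il13 (2.53) and Fam46a (2.35) were also higher at 4 of 4 times without passing. Lower with IL-2 at 4 of 4 times, also without passing, were Serpinb5 (-3.11), Cxcr1 (-3.04), Hlx (-2.44), Trib2 (-2.26), Tha1 (-2.26), Tgfb3 (-2.18), Csf1 (-2.14) and Mxd1 (-2.13). Of these 16 genes, Tha1 came closest to the threshold (edgeR adjusted p = 0.0946).

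Of 25 gene lists with enough tested members, 16 passed camera's test at its preset correlation and 0 passed with an estimated correlation or with fry's directional test, so each of the following stands with that limit. Fry's mixed test, which asks whether members differ in either direction, passed 7 lists: immediate early genes (fry mixed adjusted p = 0.00452), Treg genes and apoptosis regulators (fry mixed adjusted p = 0.0314 each), and STAT5 targets, STAT3 targets, Th2 genes and ATF4 targets (fry mixed adjusted p = 0.0317 each). Zfp36, on the immediate early list, was the only list member that passed over all genes tested. Th2 genes were higher with IL-2 (median 1.90; camera adjusted p = 4.6e-14; adjusted p = 0.361 with an estimated correlation), with 6 of 6 higher adjusted over the list alone. STAT5 targets were higher (median 0.84; camera adjusted p = 1.65e-09; adjusted p = 0.374 with an estimated correlation), with 14 higher and 2 lower of 22 adjusted over the list alone. Ribosome biogenesis genes (median 0.58; camera adjusted p = 1.02e-09; adjusted p = 0.469 with an estimated correlation) had 11 of 18 higher adjusted over the list alone, and ATF4 targets (median 0.59; camera adjusted p = 1.16e-07; adjusted p = 0.374 with an estimated correlation) 6 of 12. STAT3 targets were lower with IL-2 (median -0.93; camera adjusted p = 2.35e-10; adjusted p = 0.361 with an estimated correlation), with 12 lower and 2 higher of 16 adjusted over the list alone. Th1 and cytotoxic genes were lower (median -0.79; camera adjusted p = 0.000103; adjusted p = 0.469 with an estimated correlation), with 6 lower and 1 higher of 16 adjusted over the list alone.

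Tfh genes were lower with IL-2 (median -0.45; camera adjusted p = 0.00162; adjusted p = 0.469 with an estimated correlation), with 5 lower and 1 higher of 10 adjusted over the list alone. Th17 genes (median -0.57; camera adjusted p = 0.00387; adjusted p = 0.374 with an estimated correlation) had 2 of 4 lower, and JAK-STAT components (median -0.38; camera adjusted p = 8.72e-05; adjusted p = 0.469 with an estimated correlation) 2 of 14 lower, both adjusted over the list alone. For 5 further lists 0 members passed adjusted over the list alone. Cell cycle genes (median 0.41; camera adjusted p = 3.22e-05), cholesterol synthesis genes (0.59; camera adjusted p = 4.64e-06) and glycolysis genes (0.47; camera adjusted p = 0.000896) were higher with IL-2. Naive and quiescence genes (-0.49; camera adjusted p = 3.32e-05) and interferon-stimulated genes (-0.39; camera adjusted p = 0.00426) were lower. Each of these 5 had camera adjusted p = 0.525 with an estimated correlation. B cell markers (0.36; camera adjusted p = 0.0357; 0 passing adjusted over the list alone) and CD4 T cell markers (-0.28; camera adjusted p = 0.0345; 1 lower adjusted over the list alone) also passed, each with adjusted p = 0.525 with an estimated correlation.

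The other lists did not pass camera. Housekeeping genes had camera adjusted p = 0.0745 and nuclear RNAs camera adjusted p = 0.0954, with 0 higher and 1 lower of 9 nuclear RNAs adjusted over the list alone. Receptors of the common gamma chain family had camera adjusted p = 0.328 (1 higher and 2 lower adjusted over the list alone) and apoptosis regulators camera adjusted p = 0.818 (3 higher and 3 lower). Immediate early genes went both ways, 6 higher and 4 lower of 17 adjusted over the list alone, with a median of 0.25, a mean of -0.01 and camera adjusted p = 0.566. Treg genes had a median of -0.24 and a mean of 0.06 (camera adjusted p = 0.566; 3 higher and 1 lower adjusted over the list alone). Macrophage markers had camera adjusted p = 0.327. NK markers had a median of -0.26 against a mean of 0.17 and camera adjusted p = 0.737. CD8, dendritic and erythroid markers had too few tested members for camera.

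Between 0.5 and 24 h, 27 genes changed over both cytokines in edgeR's quasi-likelihood test, 3 rising and 24 falling; all were chosen for naming after their values were seen. Igfbp4 rose by 3.37 (SE 0.30; edgeR adjusted p = 0.0202), Lama5 by 3.21 and Tmem158 by 3.03. The genes that fell included Fosb (-6.54, SE 0.45; edgeR adjusted p = 0.0174), Cd69 (-3.68), Gadd45b (-2.89), Nfkbia (-2.83; edgeR adjusted p = 0.0272), Tnfaip3 (-2.71), Tagap (-2.71) and Bhlhe40 (-2.19). These values are fitted to counts without the added 1 RPKM, so they are not on the scale of the 2-library differences. Fosb was at 0.07 and 0.08 RPKM after 24 h of IL-2 and IL-21, with 12 reads for IL-21, so the size of its fall rests on few reads. The metallothionein genes Mt2 (-2.72) and Mt1 (-2.30) fell, as did the transcription factor gene Klf4 (-4.03) and the dendritic and B cell activation marker gene Cd83 (-2.81). Hspa1a (-3.13) and Hspa1b (-2.61), heat shock genes that are near-identical copies, are uncertain singly. At an unadjusted p under 0.05 the count was 2129, limma gave 46 genes and DESeq2 840, and without the 4 h libraries edgeR gave 0 (1713 unadjusted). B cell markers were lower in both 24 h libraries, and no library without cytokine at 24 h was compared.

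The genes that differed from control under IL-2 and under IL-21 overlapped. At 0.5 h 20 genes were at or over 2-fold higher with both, and 1 was lower with both. Values in brackets are the overlap of gene sets picked independently, which leaves out the shared control (0.1 for the higher genes at 0.5 h). At 2 h 111 genes were higher with both (5.9) and 65 lower with both (1.7). At 4 h the shared numbers were 59 higher (7.2) and 92 lower (4.8), and at 24 h 34 higher (17.1) and 93 lower (13.7). Of 22 genes at or over 2-fold on opposite sides of control at 24 h, 19 were lower with IL-2 and higher with IL-21. Across genes, which are not independent replicates, the differences from control had Pearson's r of 0.232, 0.788, 0.632 and 0.304 at 0.5, 2, 4 and 24 h. Unchanged libraries simulated around 1 shared control gave about 0.499, a value that equal noise in all libraries sets. On average they gave 0.0 genes at or over 2-fold with both at each time. Their noise was normal, with the typical spread of the cytokine difference at 0.5 h, so 2-fold was hardly reachable. The 0.0 therefore sets no baseline for outlying values of the control, and the real differences are left out. The simulated covariance of about 0.0184 lay above the observed 0.0098 at 0.5 h. It lay under the observed 0.1561, 0.1505 and 0.1025 at the later times. Part of any excess may come from the shared control. Against the 0.5 h library of the same cytokine, which shares no library between the series, r was 0.774, 0.464 and 0.271 at the later times.

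**Figure D4:**
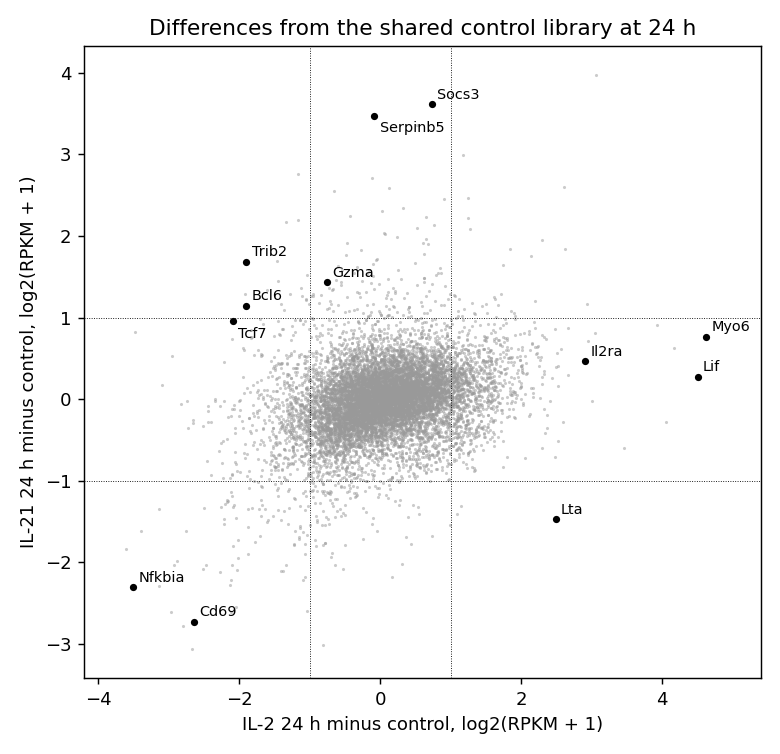
Each point is a gene, with its log2(RPKM + 1) difference from control after 24 h of IL-2 (horizontal axis) and of IL-21 (vertical axis), 1 library each, and dotted lines at 2-fold. Genes such as Tcf7 and Bcl6 lie to the lower side for IL-2 and the higher side for IL-21, and Nfkbia and Cd69 are lower with both; r across genes was 0.304.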

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

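The split test and the restriction to 4 and 24 h in this part were chosen only after the result was seen. Hbegf and Tnf were singled out because their levels differed between the cytokines over the 4 times in edgeR's quasi-likelihood test, by 3.34 and 2.4 (log2) in favour of IL-2, and Zfp36 and Sgk1 because they differed the other way, by -2.15 and -1.83. Hbegf stood at 3.11 RPKM on average with IL-2, at 0.332 with IL-21 and at 0.331 in control, so its difference lies on the IL-2 side. Sgk1 stood at 5.68, 19.8 and 2.99 RPKM. For Tnf (32.6, 6.32 and 10.9 RPKM) and Zfp36 (18.7, 77.9 and 38.1 RPKM) the control lay between the means of the cytokines. This did not hold at every time. Tnf was above control with both at 0.5 h (44.8 and 11.3 RPKM), and Zfp36 was below it with both at 2 h (8.4 and 33.1 RPKM).

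Over all splits of the 8 cytokine libraries into 4 and 4, the share does not decide whether chance gave this count. Of 32 that could be fitted, 3 gave at least the 4 genes of the real split, itself included. The other 2 gave 1821 genes each and set IL-2 against IL-21 at 4 and 24 h. They hold the real cytokine difference at those times, so they do not stand for chance. Among the 8 splits that part the libraries of every time, the real one gave 4 genes and the other 7 gave 0 in edgeR. Since 8 splits are too few for a share under 0.05, chance is not excluded. The fit of a cytokine difference at 4 and 24 h only restates these 1821 genes (900 higher with IL-2, 921 lower) and tests nothing further, since its error comes largely from the differences at 0.5 and 2 h, already seen to be small, and the other 5 pairs of times gave 0 genes (22 to 1115 at an unadjusted p under 0.05), with no other tool run.

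A further 7 of the 179 named genes lay on opposite sides of the control, in all 4 libraries of each cytokine, a difference that was not tested. Akr1c18, a steroid-metabolising enzyme gene, was above control with IL-2 and below it with IL-21 (mean difference between the cytokines 2.622, log2). The others were below control with IL-2 and above it with IL-21: the Tribbles pseudokinase gene Trib2 (-2.081), the MYC antagonist gene Mxd1 (-1.92), Tha1 (-1.89), the death-promoting gene Bcl2l11 (-1.515), Tgfb3 (-1.511) and the granzyme gene Gzma (-1.186). Some of these values lie close to control, such as Trib2 at -0.045 and Tha1 at -0.01 in their nearest IL-2 library. Across all 11047 genes, 106 showed such opposite signs, 51 of them above control with IL-2. Bcl2l11 and Gzma are list members, and the other 5 are in the named set for their difference between the cytokines, which favours opposite signs.

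Ribosomal precursor RNA is outside the gene comparisons. Its entry Rn45s reached 1890.8 RPKM in the library of IL-2 at 2 h against 1344.2 in control, and stood at 771.1 RPKM with IL-2 at 4 h. It made up 1.103% of the total reads at 2 h and 0.784% in control.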

How the results depend on the processing

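DESeq2, edgeR's robust option, the restriction to 4 and 24 h and the requirement on counting intervals were chosen only after the results were seen. For the counts of genes and lists, 117 values lay within 1.5 times the reported count and 29 did not. Under median-ratio scaling all 224 list medians against control moved by less than 0.1. Upper quartile scaling turned the sign of some medians close to 0, such as Th1 and cytotoxic genes with IL-2 at 24 h (0.042 to -0.097) and NK markers in the same library (0.059 to -0.084). Values of named genes from 2 libraries stayed within counting error 190 times, moved 228 times and reversed 2 times: against the 0.5 h library of the same cytokine instead of the control, Lif with IL-2 at 2 h gave -0.134 and Socs3 with IL-21 at 2 h -0.225, because both were already high at 0.5 h. No paired analysis was possible because the labels tie no libraries to a shared mouse or culture; pairing was by time alone, which the reported fits hold as a factor.

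With a pseudocount of 0.1, which shrinks low genes less, the counts at or over 2-fold were 98, 855 and 1524 for IL-2 at 0.5, 2 and 4 h, 82, 616, 559 and 749 for IL-21 at 0.5, 2, 4 and 24 h, and 122, 265 and 767 for IL-2 against IL-21 at 0.5, 2 and 4 h. Keeping short RNAs gave 66 for IL-21 at 0.5 h and 101 for IL-2 against IL-21 at 0.5 h. Depth sets the limit for low genes, since 3 reads in 1 kb are worth up to 0.102 RPKM.

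The 4 genes of IL-2 against IL-21 became 19 without a filter, 447 with DESeq2 (246 higher, 201 lower), 123 without the 0.5 h libraries and 1821 with the difference at 4 and 24 h only, which makes the 0.5 and 2 h differences error. Without that pairing by time 1 gene passed, sharing 0 with the 4 genes. In edgeR 0 passed without the 4 h libraries (690 at an unadjusted p under 0.05) and 0 without the 24 h libraries (1060 unadjusted), where fewer libraries were fitted; limma gave 3 and DESeq2 447 on all libraries. Hbegf did not pass with limma at a pseudocount of 1. Upper quartile and median-ratio scaling, averaged transcripts, the robust option and leaving out the 2 h libraries kept all 4.

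The 27 genes between 0.5 and 24 h became 46 with limma, 49 and 46 with limma at pseudocounts of 0.1 and 0.5, 145 without a filter, 12 with a mean of at least 5 RPKM, 66 with upper quartile scaling and 840 with DESeq2 (385 higher, 455 lower). In edgeR 0 passed without the 4 h libraries (1713 at an unadjusted p under 0.05). Of the 25 lists, 16 passed camera, 0 with an estimated correlation and 0 with fry's directional test (7 with its mixed test, for differences in either direction). Apart from fewer libraries or genes tested, the cause was not tested.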

Other observations

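All tests in this part except thinning the reads and removing the trend on transcript length were chosen only after the result was seen. Some genes were lower than control under both cytokines. At 2, 4 and 24 h alike, 22 genes were at or over 2-fold lower with IL-2 and with IL-21, and they were chosen after their values were seen. Among them are the NF-kappaB feedback genes Nfkbia and Tnfaip3, the activation markers Cd69, Cd83 and Cd274, the AP-1 gene Fosb, and Gadd45b, Irf1, Cxcl10, Cxcr4, Bhlhe40, Tagap and Mxd4. Others are Rec8, Rilpl2, Osgin1, Grap and Dapk2, and no shared theme was tested. Nfkbia stood at 292 RPKM in control and at 40.0 and 55.0 RPKM after 2 h of IL-2 and IL-21. Cd69 was higher than control at 0.5 h (104 and 121 against 63.6 RPKM) before it was lower at 2 h (12.8 and 10.2 RPKM).

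A control library out of place is argued against, because the 22 genes had a median difference from it of only -0.08 in the 0.5 h libraries. Loss of B cells is argued against as well, by the median of 4 abundant B cell markers. That median was -0.165 at 2 h, when the 22 genes were at -1.337 with IL-2 and -1.468 with IL-21. The markers were split, though. Cd79b was at 10.0 and 5.7 RPKM after 2 h of IL-2 and IL-21, against 16.5 in control. Cd79a was at 9.1 RPKM with each cytokine against 11.7, and Ms4a1 at 13.8 and 15.2 against 13.8. An effect of the cytokines and an effect of time in culture cannot be told apart, since 0 libraries without cytokine at 2, 4 or 24 h were compared. No further biological explanation was tested.

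B cell markers were lower than control at 24 h, 9 of 9 in both cytokine libraries, with medians of -0.76 for IL-2 and -1.44 for IL-21. Fewer B cells in the 24 h cultures and, in the IL-2 library, dilution by more RNA from grown T cells cannot be told apart, since the 9 of 9 is the observation itself and no cell counts were compared. The markers were higher with IL-2 than with IL-21 by a median of 0.87, which compares the cytokines and decides nothing about the IL-2 library alone. In that library the medians of macrophage (-0.565), dendritic (-0.633) and erythroid (-1.01) markers were lower too, as was that of CD4 T cell markers (-0.701). No biological explanation was tested.

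The large count for IL-2 at 24 h, 1791 genes, was set against technical explanations. Transcript length and scaling are argued against as its whole cause, because removing the trend on length left 1783 genes and upper quartile scaling left 1730, though with 668 higher and 1062 lower. Depth is argued against as its whole cause too. The shallowest library, IL-2 at 0.5 h with 29.5 M reads, differed from control in 48 genes, while IL-2 at 24 h had 31.0 M reads. The counting intervals excluded equal levels for 1791 of the 1791 genes. A gene at 2-fold after adding 1 RPKM nearly always has enough reads for that, so the intervals cannot decide. Thinning to the shallowest library left 1794 but kept 85.8% and 95% of the reads, too many to decide. In the simulation with counting noise alone, at the depth of the control library, 0 unchanged genes were called. Time in culture alone is argued against, because IL-2 and IL-21 at the same 24 h differed in 1757 genes, where IL-21 differed from control in 385. A response to IL-2, with or without a part from time in culture, and a difference peculiar to this 1 library stay open.

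A hypothesis concerns how long a shared response lasts. Of the 111 genes at or over 2-fold higher at 2 h with both cytokines, 70 were still so at 24 h with IL-2 and 12 with IL-21. To avoid a head start for IL-2, the test used the 31 genes within 0.25 (log2) of each other at 2 h. At 24 h their median difference was 0.753 in favour of IL-2 (quartiles 0.292 and 1.028), and 25 of 31 were higher with IL-2. Between the same 2 libraries the median of all genes was 0.069. That of housekeeping genes was 0.742, with 13 of 14 higher with IL-2. Upper quartile scaling moved the median of all genes by -0.177 in this comparison. Against control, 15 of the 31 were still at or over 2-fold with IL-2 (median 0.966, after 1.241 at 2 h) and 0 with IL-21 (0.524, after 1.131). A response that both cytokines start may fade less by 24 h with IL-2 than with IL-21. The hypothesis was found and tested on the same libraries. Housekeeping genes differed by nearly as much, so the difference at 24 h is not particular to genes of the shared response.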
